A study of Mus musculus with 2 samples.

How the data were processed

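Total RNA of more than 200 nt from liver of B6NCrl mouse embryos at day 13.5, pooled from both sexes, was sequenced in 2 libraries, each from 10 ng of RNA of a separate tissue sample with a spike-in mix added, per the labels. RNA was extracted with a mirVana kit, and the manual of a SMARTer Ultra Low kit is among the protocols linked, per the labels' protocols. The aligner and the quantification tool are not given in the sources used here, although the column names are those that RSEM writes. Strand use in counting is not given in the sources used here.

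Each library came with a table of genes and a table of transcripts. Per the deposited readme, reads were assigned to the mouse build mm10 with GENCODE release M4, and each table describes 1 library. The expected counts are estimates of reads per gene in which the authors' model divides reads that fit several genes, per the file headers, and they carry a posterior SD. TPM values were normalised by the authors to a fixed sum per library over genes, transfer RNA entries and spike-ins together, with an effective length 99 nt below the transcript length. FPKM columns are present per the file headers and gave no printed value. The percent of a gene's expression in each transcript is deposited as a column and was recomputed from TPM here.

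Of the 43346 annotated genes, 42462 received a symbol by gene ID from GENCODE release M21, and the remaining 884 held 0.154% and 0.163% of gene counts. Where a symbol had more than 1 gene ID, the more abundant gene was used. Coordinates are those of release M21 on GRCm38, the assembly that mm10 names. The 96 spike-ins and 26248 transfer RNA entries were left out of gene totals. Hbb-b1, Hbb-b2, C5, Muc16, Rn7sl1, Snhg1 and Rn45s had no entry under these symbols and were left out of their lists, 7 members in all.

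The labels define 1 group, so levels are given as mean and SD over n = 2 biological replicates and no p-value was computed. The 31 gene lists, the 17 genes for isoforms, the results and their alternatives were fixed before the data were examined. Named genes were the 20 with the highest mean TPM, the 3 highest members of each list, members of a list below 1 TPM that are counted, the genes of the fixed comparisons, and the 5 highest and 5 lowest log2 ratios between replicates among genes with at least 100 counts in both. The 20 were taken among genes with a symbol, a length of at least 200 nt and an annotated nuclear or mitochondrial location. Ass1, Epcam, Spp1, Uty and Kdm5d and the genes of lists added later were chosen after their values were seen. List levels are the median log2(TPM + 0.1) or the median TPM. A few genes that this rule names are not reported here. The list named for lung and heart holds 7 cardiac genes.

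Ratios between replicates were computed as log2 of expected counts plus 0.5 with TMM factors for genes with a mean count of at least 10 (15885 genes), and without the added 0.5 for the extreme genes. Each list median was set against 10000 random lists of the same size drawn from 20 bins of mean TPM. As alternatives chosen after the data were seen, medians of 20 bins of transcript length, of GC content or, in 3 rounds, of both were subtracted from the ratios first. Counting intervals are exact 95% binomial intervals of the ratio of 2 counts. They and the floor of 3 counts cover counting error only, since the reads carried no molecular identifiers in the files. The precision of a ratio falls with the count, so those of low genes are wide.

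Expected counts were rounded for edgeR 4.0.16 (TMM, filterByExpr, common dispersion with an intercept only) and DESeq2 1.42.0 (size factors and dispersion as alternatives) in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The dispersion step was tested on simulated counts of 15447 genes, where coefficients of 0.05, 0.1 and 0.2 were recovered as 0.0499, 0.1 and 0.2. The list step was tested on simulated counts of 15885 genes with 200 changed ones in lists of 50. True log2 changes of 0.32, 0.58, 1 and 2 gave medians of 0.28, 0.58, 1.01 and 2.09, and 5 of 100 unchanged lists lay outside the central 95%. The fixed lists held 3 to 32 genes with a ratio, fewer than the simulated ones. Genes of the random lists were drawn independently, whereas members of a fixed list may vary together. The 5 of 100 therefore need not hold for the fixed lists. Alternatives covered the pseudocount, filters on low values, counts against TPM, posterior mean TPM, the scaling and each replicate alone.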

Results

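Transcript levels of whole liver were measured at embryonic day 13.5 in B6NCrl mice, a stage at which the liver is the main blood-forming organ of the fetus. The libraries came from pools of male and female embryos, and the 2 biological replicates were separate tissue samples of 1 group that share 1 donor entry, so the SD over n = 2 measures only the spread between these samples. No second tissue, age or treatment was part of the series, so the comparisons are between gene groups within the libraries and between the replicates, and no test of a condition was possible. Each library was made from 10 ng of total RNA longer than 200 nt with added spike-in RNAs. Replicate 1 held 39644066 expected counts and replicate 2 held 38150988, of which 39182457 and 37432977 fell on annotated genes. A count of 0, which allows up to 3 counts, corresponded for a transcript of 2000 nt to at most 0.0417 TPM in replicate 1 and 0.0464 TPM in replicate 2. In all, 12183 annotated genes reached 1 TPM, the transcript abundance corrected for length and library size, in both libraries, and 11194 of these were protein-coding. Levels below are the mean ± SD of the 2 replicates.

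Globin transcripts dominated the tissue. The 7 measured globin genes made up 32.9% ± 2.43 of the TPM of all annotated genes, and the 4 highest genes of the libraries were all adult globins. Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298 of the GRCm38 assembly) stood at 132913 ± 10117 TPM and Hba-a1, its neighbour on chromosome 11, at 54337 ± 4995 TPM. Hbb-bs and Hbb-bt, the adult beta-type genes of the cluster on chromosome 7, stood at 64884 ± 5121 and 64784 ± 5791 TPM. The members of each pair are nearly identical, so their reads were divided by a model, with a posterior SD of 1300 counts on 2.41e+06 counts for Hba-a2 in replicate 1. Taken over expected counts, which grow with transcript length, their share was 15.2% ± 1.85.

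The embryonic globins, which are expressed by primitive red cells, were present at much lower levels. Hbb-y (chromosome 7, 103851749 to 103853216) stood at 3249 ± 612 TPM, Hbb-bh1 at 359 ± 45.1 TPM and Hba-x at 325 ± 92.2 TPM. Together they made up 1.22% ± 0.132 of all globin transcripts, with 1.31% in replicate 1 and 1.13% in replicate 2.

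**Figure D1:**
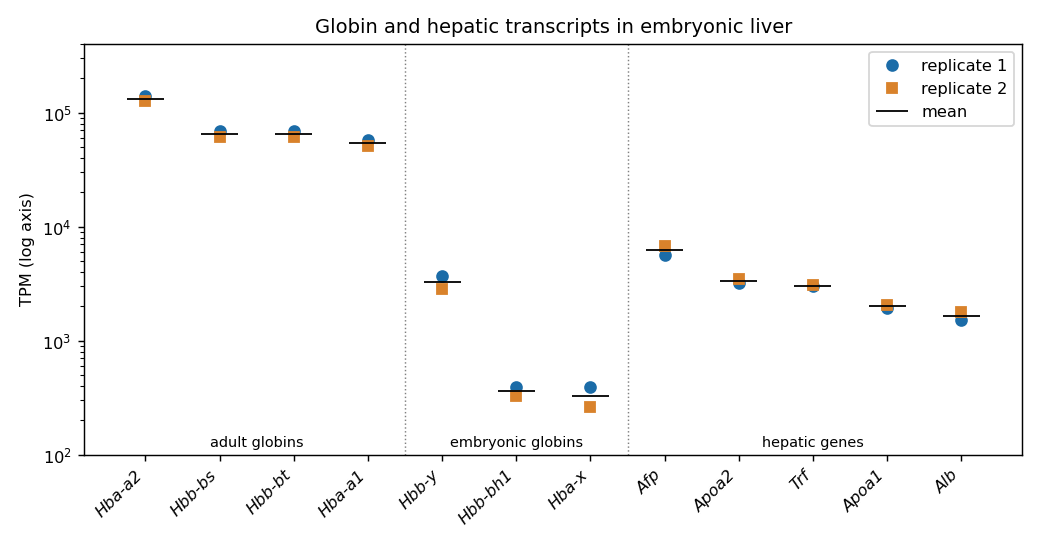
TPM (log axis) of the 4 adult globins, the 3 embryonic globins and 5 abundant hepatic genes, with 1 point per replicate and a line at the mean. Each adult globin lies above every hepatic gene shown, of which Afp is the highest at 6219 TPM.

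The rest of the red cell program was also abundant, and every member of its 3 lists exceeded 1 TPM in both libraries. The 15 genes of heme synthesis and iron uptake had a median of 263 ± 36.7 TPM. They included Alas2, the first enzyme of heme synthesis in red cells, at 892 ± 19.2 TPM, and Alad at 571 ± 28.2 TPM. The 15 genes of the erythroid membrane and cytoskeleton had a median of 151 ± 28.1 TPM, with the anion exchanger Slc4a1 at 739 ± 111 TPM and Rhd at 496 ± 7.89 TPM. Among the 16 erythroid regulators, with a median of 34.0 ± 1.12 TPM, Klf1 was highest at 431 ± 17.4 TPM, followed by Nfe2 at 159 ± 8.65 TPM and Lmo2 at 145 ± 6.38 TPM. Gata1, the central transcription factor of red cell development, stood at 126 ± 6.13 TPM. Ferritin transcripts, which encode the iron store of the cell, were among the 20 highest genes of at least 200 nt. Ftl1 stood at 7141 ± 432 TPM and Fth1 at 4886 ± 43.1 TPM.

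Hepatic transcripts formed the next layer. The union of the hepatoblast list and the list of coagulation and complement genes took 2.50% ± 0.221 of TPM. Alpha-fetoprotein (Afp, ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907) was the highest at 6219 ± 832 TPM, followed by the apolipoprotein Apoa2 at 3354 ± 190.2 TPM and transferrin (Trf) at 3043 ± 15.3 TPM. Albumin (Alb, chromosome 5, 90460897 to 90476602) stood at 1660.2 ± 183 TPM, so that the log2 ratio of Afp over Alb was 1.90 ± 0.03 within a library. Of the 32 hepatoblast genes, 30 exceeded 1 TPM in both libraries, and the 2 that stayed below were the transcription factors Foxa1 and Onecut2. Hnf4a, a transcription factor that defines hepatic fate, stood at 12.4 ± 1.91 TPM. The 19 measured coagulation and complement genes had a median of 52.2 ± 1.82 TPM, led by antithrombin (Serpinc1) at 318 ± 36.4 TPM, kininogen (Kng1) at 261 ± 8.44 TPM and plasminogen (Plg) at 144 ± 32.2 TPM. C9 and F9 remained below 1 TPM in both libraries.

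Genes of mature hepatocyte metabolism were low as a group but not uniformly so. Their median log2(TPM + 0.1) differed from that of the hepatoblast list by −8.72 ± 0.17. Of the 30 members, 11 exceeded 1 TPM in both libraries and 19 were below 1 TPM in both. The abundant members included the fatty acid-binding protein Fabp1 at 212 ± 18.5 TPM and glutamine synthetase (Glul) at 101 ± 0.424 TPM. Of the genes encoding enzymes of the urea cycle, Ass1 stood at 72.7 ± 7.22 TPM and Cps1 at 0.37 and 0.40 TPM in replicates 1 and 2. The gluconeogenic genes Pck1 and G6pc were at or below 0.22 TPM in both libraries, and Cyp7a1, the first enzyme of bile acid synthesis, was at 0.24 TPM in each. Cyp2c29, Serpina3k, Mup3 and Mup20 had no count in either library. The Mup genes and Serpina3k belong to families of close copies, so their counts were less certain.

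Genes of other blood lineages were also present. The 15 granulocyte and monocyte genes had a median of 44.6 ± 0.382 TPM and all exceeded 1 TPM in both libraries. S100a8 stood at 436 ± 31.1 TPM, myeloperoxidase (Mpo) at 259 ± 13.2 TPM and S100a9 at 195 ± 13.4 TPM. The 14 megakaryocyte genes had a median of 22.5 ± 0.442 TPM, led by the platelet chemokines Pf4 at 463 ± 42.1 TPM and Ppbp at 192 ± 7.81 TPM and by the integrin Itga2b at 39.7 ± 2.43 TPM. The 19 macrophage and Kupffer genes had a median of 15.1 ± 0.778 TPM, and the highest were Hmox1, C1qb and Vcam1 at 67.7 ± 4.36, 62.0 ± 2.01 and 46.5 ± 6.58 TPM. Stem and progenitor genes were lower, with a median of 3.32 ± 0.343 TPM over 16 genes, and were led by Cd34, Kit and Meis1 at 15.6 ± 2.2, 12.5 ± 2.55 and 10.5 ± 1.18 TPM.

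Mast cell and lymphoid genes were low. The mast cell and basophil list had a median of 0.755 ± 0.0636 TPM, with Hdc at 6.93 ± 0.361 TPM, Cpa3 at 5.84 ± 0.559 TPM and Mcpt8 at 2.44 ± 0.651 TPM. The B lymphoid list had a median of 0.21 TPM in each library and 12 of its 13 members below 1 TPM in both, Cd79b being the exception at 3.64 ± 0.453 TPM. The T and NK lymphoid list had a median of 0.065 ± 0.00707 TPM, with only Lck at 3.33 ± 0.191 TPM and Gata3 at 1.35 ± 0.0354 TPM above 1 TPM in both libraries.

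Genes listed for supporting cells of the liver were at moderate to low levels. The libraries are of whole tissue, so no cells are named from these lists. The 16 sinusoidal endothelial genes had a median of 6.66 ± 1.11 TPM, with Lyve1 at 25.3 ± 4.72, Oit3 at 20.4 ± 0.827 and endoglin (Eng) at 19.7 ± 1.68 TPM. The 17 stellate and mesenchymal genes had a median of 4.55 ± 0.099 TPM, although the collagens Col3a1, Col1a1 and Col1a2 reached 116 ± 7.52, 75.6 ± 1.38 and 48.8 ± 0.474 TPM. The mesothelial list had a median of 1.8 ± 0.170 TPM over 7 measured genes, and its leading members were Upk3b, Gpm6a and Aldh1a2 at 4.94 ± 0.453, 2.88 ± 0.537 and 2.15 ± 0.502 TPM. The cholangiocyte list, named for bile duct cells, had a median of 1.76 ± 0.336 TPM, led by Krt7 at 3.55 ± 1.34, Krt19 at 3.1 ± 1.07 and Sox4 at 3.07 ± 0.919 TPM. Of its 10 members, 5 reached 1 TPM in both libraries.

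Transcripts of dividing cells were abundant. All 24 proliferation genes exceeded 1 TPM in both libraries, with a median of 178 ± 8.59 TPM, and the highest were the ribonucleotide reductase subunit Rrm2, survivin (Birc5) and Pcna at 581 ± 75.5, 379 ± 17.9 and 346 ± 20.4 TPM. The 20 imprinted genes had a median of 24.0 ± 2.18 TPM, and 18 exceeded 1 TPM in both libraries. Dlk1, H19 and Igf2 were the highest of them at 444 ± 21.2, 346 ± 31.7 and 334 ± 7.67 TPM. The fetal RNA-binding group was led by Igf2bp1 at 20.2 ± 1.34, Igf2bp3 at 17.7 ± 1.83 and Igf2bp2 at 13.1 ± 3.07 TPM, with a group median of 13.1 ± 3.07 TPM over 5 genes. The handling stress list, made of immediate early and heat shock genes, had a median of 4.89 ± 0.58 TPM and was led by Btg2, Dusp1 and Ier2 at 75.7 ± 5.75, 22.3 ± 3.22 and 20.0 ± 2.21 TPM. Housekeeping genes had a median of 778 ± 26.7 TPM, with Ppia, Actb and Eef1a1 at 3446 ± 135, 3020.3 ± 119 and 2426 ± 58.8 TPM.

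**Figure D2:**
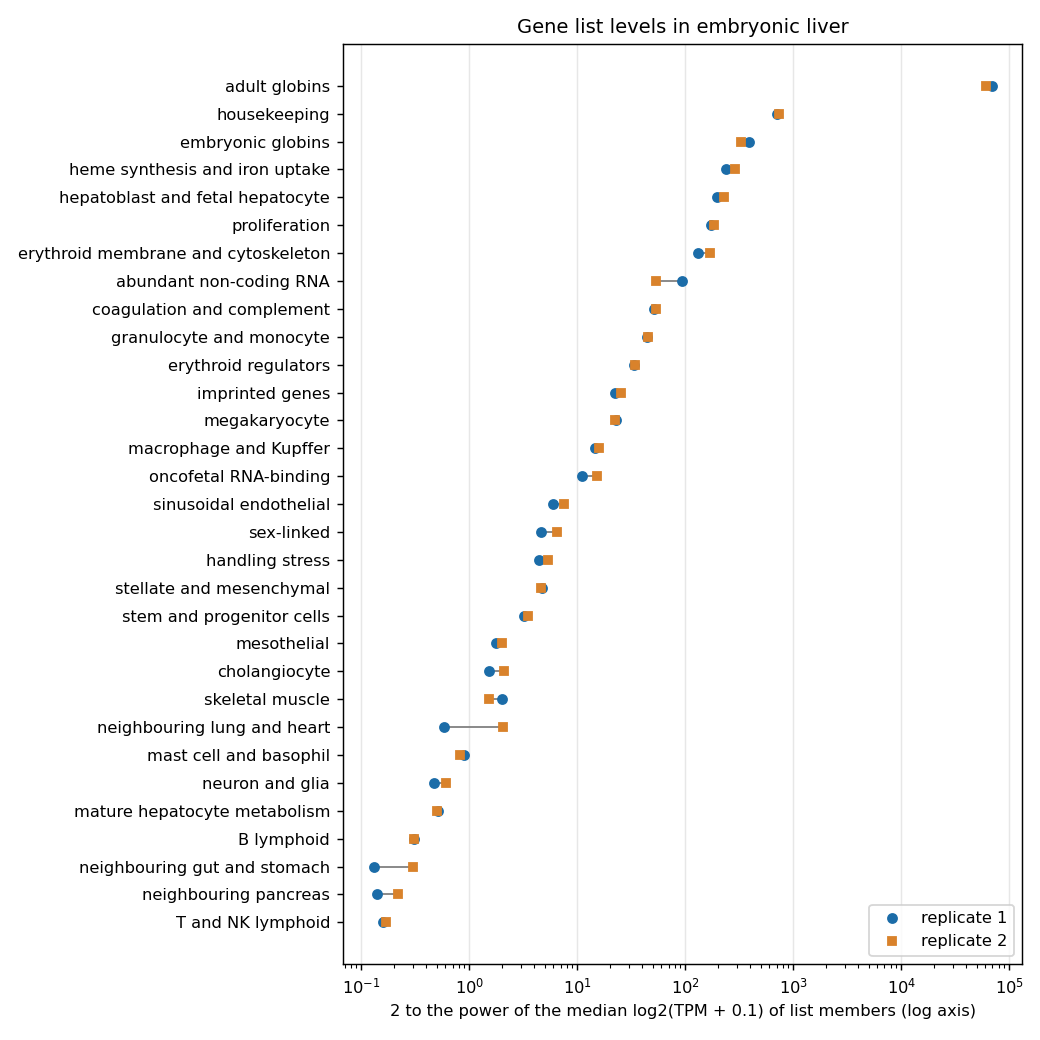
Level of each of the 31 gene lists in each replicate, as 2 to the power of the median log2(TPM + 0.1), on a log axis. Adult globins lie at the top, lymphoid, gut and pancreas lists at the bottom, and the lung and heart list has the widest gap between the replicates, with median TPM of 0.485 and 2.24.

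Markers of tissues next to the liver were low beside the hepatoblast list, with a difference between the replicates for heart. Among 13 lists of resident cell types, which left out the higher globin and heme synthesis lists, hepatoblast and fetal hepatocyte was the highest. It exceeded the highest of the neighbouring tissue lists by 6.71 ± 0.13 on the log2(TPM + 0.1) scale, a lead over skeletal muscle in replicate 1 (6.62) and over lung and heart in replicate 2 (6.80). The lowest resident lists had no such lead. The skeletal muscle median of 1.69 TPM lay near those of cholangiocyte (1.76) and mesothelial (1.8) genes and above that of mast cell and basophil genes (0.755). In replicate 2 the lung and heart median (2.24) exceeded those of cholangiocyte (1.995) and mesothelial (1.92) genes. In replicate 1 it was lower (0.485 against 1.52 and 1.68). The gut and stomach list had a median of 0.115 ± 0.12 TPM, and Barx1 at 1.06 ± 0.0566 TPM, Gata5 at 0.745 ± 0.0778 TPM and Vil1 at 0.665 ± 0.148 TPM were its highest members. The pancreas list had a median of 0.08 ± 0.0566 TPM, with Cela1 at 5.51 ± 0.834 and Cpa1 at 0.865 ± 0.573 TPM. The neuron and glia list had a median of 0.443 ± 0.0955 TPM, with Stmn2 at 3.83 ± 1.71, Tubb3 at 1.52 ± 0.304 and Map2 at 1.01 ± 0.262 TPM. The skeletal muscle list had a median of 1.69 ± 0.354 TPM, with Mylpf at 34.3 ± 3.32, Acta1 at 12.3 ± 4.36 and Actn2 at 3.22 ± 0.0778 TPM. In the lung and heart list, cardiac actin (Actc1) stood at 23.0 TPM in replicate 1 and 53.7 TPM in replicate 2, Myl7 at 8.93 and 12.8 TPM, and cardiac troponin T (Tnnt2) at 3.82 and 17.2 TPM, whereas the lung genes Nkx2-1 and Sftpc had at most 3 counts.

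Other classes of RNA took small shares. The genes encoded on the mitochondrial genome held 1.71% ± 0.184 of the counts of annotated genes, with mt-Atp6 at 5682 ± 257 TPM and mt-Atp8 at 4532 ± 559 TPM. Part of this signal could not be placed, because Gm28437, a nuclear copy of mitochondrial sequence (chromosome 1, 24613189 to 24613971), was listed at 4838 ± 1092 TPM with a posterior SD of 41873 counts on 145332 counts in replicate 1. Rn7s1 and Rn7s2, identical copies of the RNA of the signal recognition particle, were each at 6024 TPM with SDs of 1368 and 1366 TPM. Among the 7 measured abundant non-coding RNAs, whose median was 73.4 ± 28.2 TPM, Malat1 stood at 1215 ± 86.8, Gas5 at 412 ± 5.84 and Rn7sk at 108 ± 45.1 TPM. The glutathione peroxidase Gpx1 at 6186 ± 15.6 TPM, the histone gene Hist1h2ap at 4662 ± 296 TPM and metallothionein (Mt1) at 3526 ± 434 TPM completed the 20 highest genes of at least 200 nt.

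The transcript tables were used to ask which isoform prevailed for 17 genes fixed in advance. In 16 of them the transcript with the highest share of the TPM of the gene was the same in both libraries, and in 9 its mean share exceeded 80%. Klf1, Alb and Afp have a single annotated transcript. Among the others, the leading transcript held 99.6% ± 0.0791 for Slc4a1, 97.4% ± 0.516 for Gata1, 95.9% ± 0.00675 for Tal1, 95.2% ± 0.746 for Pkm, 93.8% ± 0.7 for Slc25a37 and 86.8% ± 0.345 for Hnf4a. The TPM was spread over more annotated transcripts for Runx1, where the leading transcript held 31.4% ± 2.94, for Epb41 with 37.5% ± 1.48, for Tpm1 with 36.0% ± 8.25 and for Fn1 with 41.7% ± 2.66. For Kit, Alas2 and Bcl11a it held 57.7% ± 1.67, 68.5% ± 3.31 and 50.8% ± 2.35. Over expected counts the share was 49.1% for Runx1 and 24.7% for Bcl11a-204, and Bcl11a-202 led with 38.6%. Igf2 was the exception, since its transcript Igf2-208 held 41.9% in replicate 1 and 32.3% in replicate 2, and Igf2-203 held 31.1% and 38.5%. Over expected counts their mean shares were 26.1% and 15.7%. Igf2-208 and the leading transcript of Epb41 are annotated as processed transcripts and that of Fn1 as a retained intron, so none of them is annotated as protein-coding. Shares of overlapping isoforms are estimates of the authors' model.

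The replicates resembled each other closely across genes. Over 15517 genes with at least 10 expected counts in both libraries, Pearson's r of log2(TPM + 0.1) was 0.994 and Spearman's rho 0.994, as values across genes, which are not independent replicates. The median absolute log2 ratio after TMM scaling was 0.15, and the common biological coefficient of variation from edgeR was 0.0919 over 15447 genes, against 0.0973 for the 59 spike-ins on their own totals. Spike-ins carry technical spread only, so the coefficient of the genes gives no measure of biological spread apart from the technical one. The libraries were not the same library counted again, since the chi-square statistic of their counts was 23.0 per degree of freedom. Of 11467 genes with at least 100 counts in both libraries, 99.8% differed by at most 2-fold, 11 were more than 2-fold higher in replicate 2 and 11 more than 2-fold lower.

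Spike-in RNAs were more abundant in replicate 2. They took 1.16% of all counts in replicate 1 and 1.88% in replicate 2, or 2.49% ± 0.946 of TPM, and the median log2 ratio of the 59 spike-ins with a mean count of at least 10 was 0.57 (1.48-fold) after TMM scaling. Centred on the TMM scale, endogenous genes varied less between the replicates than spike-ins of like count, with a difference of −0.33 in median absolute log2 ratio. With each class centred on its own median the difference was 0.0066, and with scaling by the spike-ins it was 0.47, so the order of the classes depended on the centring.

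Some gene groups differed between the replicates more than random lists of the same size and expression did. Heart markers were higher in replicate 2, with 7 of the 8 lung and heart genes that had enough counts above 0 and a list median log2 ratio of 2.24. Actc1, Tnnt2 and Myh7 were 2.1-fold (95% counting interval 1.96 to 2.25), 3.96-fold (3.32 to 4.77) and 5.6-fold (4.63 to 6.85) higher. The pancreas list, with 3 measurable genes, had a median of 0.92, with 2 higher and Cela1, its most abundant member, lower (−0.46). The cholangiocyte list had a median of 0.50, with 8 of 9 genes higher, among them Epcam (log2 ratio 1.51), and only Spp1 lower (−0.74). Smaller positive medians were seen for erythroid membrane and cytoskeleton (0.10) and hepatoblast and fetal hepatocyte (0.06), with 11 of 15 and 21 of 32 genes higher.

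Globin transcripts were lower in replicate 2. Embryonic globins had a median log2 ratio of −0.54 and adult globins of −0.30, with all 3 and all 4 genes lower, whereas erythroid regulators (−0.05) and genes of heme synthesis and iron uptake (−0.10) lay inside the random range. The skeletal muscle list had a median of −0.47, the sex-linked list of −0.33, granulocyte and monocyte genes of −0.24 (14 of 15 lower) and the abundant non-coding RNAs of −0.23 (6 of 6 lower). In the sex-linked list the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had log2 ratios of −0.67, −0.36, −0.30 and −0.72, and Xist had 0.48, which turns negative under scaling by the spike-ins. Xist overlaps its antisense partner Tsix, so the counts of both were less certain. In total 11 of the 31 lists lay outside the central 95% of 10000 random lists, 5 above and 6 below. Members of a list may vary together, which the random lists do not copy. The values compare 2 libraries of the same group. Ratios also rose with transcript length (Spearman's rho 0.28 across genes) and fell with GC content (−0.29), on which the random lists were not matched. With the trend of length, of GC content or of both subtracted, 11, 13 and 13 lists lay outside, 10 of them each time among the first 11. Erythroid membrane and cytoskeleton fell inside with either trend alone (0.07 and 0.02) and adult globins with both (−0.12). The hepatoblast list stayed outside in all 3 settings (0.11, 0.07 and 0.10). Lists that moved outside were heme synthesis and iron uptake with length (−0.09) and with both (−0.08), coagulation and complement with GC content and with both (0.09 each), sinusoidal endothelial (0.16) and proliferation (0.01) with GC content, and stellate and mesenchymal with both (−0.09). Scaling by the spike-ins moved the median of all genes to −0.64 and TPM ratios moved it to 0.14. Of the 5 lists above their range, the erythroid membrane, hepatoblast and cholangiocyte medians turned negative under the spike-in scaling. Lists inside their range with medians above 0 turned negative as well. As that scaling moves all genes by about the same amount, 11 lists still lay outside the random range.

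**Figure D3:**
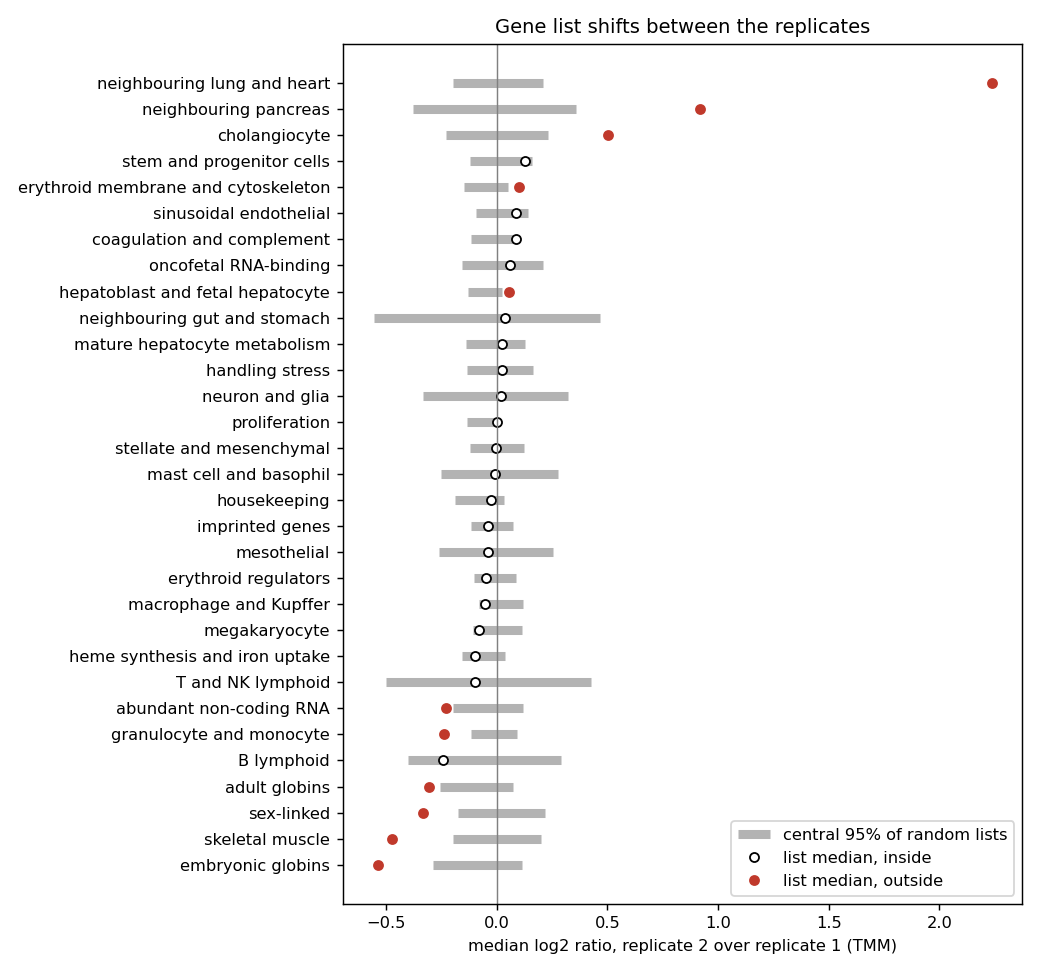
Median log2 ratio of replicate 2 over replicate 1 (TMM) for each of the 31 gene lists, with grey bars for the central 95% of 10000 random lists matched in size and expression. Filled points mark the 11 lists outside their bar, from embryonic globins at −0.54 to lung and heart at 2.24, and 3 of the 5 on the right fall below 0 under scaling by the spike-ins.

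Among genes with at least 100 counts in both libraries, the single genes that differed most included histone genes and copies that share reads. Their lowest log2 ratios were those of Gm14296 (−1.83), Hist1h3b (−1.76), Hist1h2ak (−1.72), Hist2h4 (−1.71) and Gm10273 (−1.70). Hist2h4 had 2334 counts in replicate 1 and 710.0 in replicate 2 with a posterior SD of 0, and its counting interval ran from −1.84 to −1.59. The highest under the same limit on counts were Myh7 (2.49), Gm10925 (2.33), Tnnt2 (1.99), Gm10171 (1.62) and Gm9493 (1.31). Gm10925 is a nuclear copy of mt-Atp6 with a posterior SD of 10859 counts on 1217 counts in replicate 1, and Gm10171 and Gm9493 are processed pseudogenes, so their ratios were uncertain. Gm14296 had a posterior SD of 178 counts on 418 counts in replicate 1, and Gm10273 of 137 on 657.

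**Figure D4:**
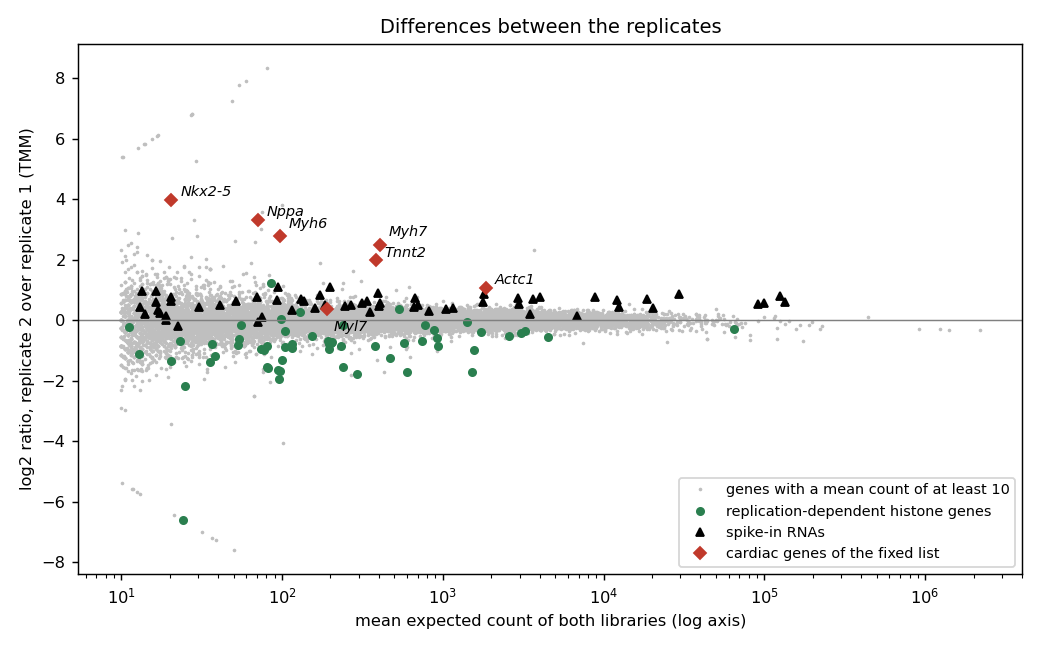
Log2 ratio of replicate 2 over replicate 1 (TMM) against the mean expected count of both libraries (log axis) for genes with a mean count of at least 10, with histone genes, spike-ins and cardiac genes marked. Most genes lie near 0, the 7 cardiac genes and most spike-ins lie above it and most histone genes below it; under scaling by the spike-ins all genes move down by about the same amount, to a median of −0.64, which takes Myl7 below 0.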

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

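The tests of skeletal muscle, shared reads, S phase and RNAs without a poly(A) tail were chosen after the results they bear on had been seen, in whole or in part, and the bounds used for shared reads and S phase were set then. The transfer RNA entries, which no comparison used, held 20.99 expected counts in replicate 1 and 23.6 in replicate 2, above the 3 counts that a count of 0 allows.

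Cardiac muscle genes were higher in replicate 2, with all 7 of the fixed list above 0 (Myl7 below 0 under scaling by the spike-ins) and a median log2 ratio of 2.48. Skeletal muscle of the body wall is argued against by its own list, whose median was −0.47. Reads shared with paralogs are argued against by the 4 cardiac genes with a posterior SD of 0, whose median was 1.53, although 32 such genes over both cardiac lists, the wider set tested first, had a median of 0.27. Heart tissue carried over with the liver of replicate 2 stays open. A second list of 30 cardiac genes, fixed before its values were seen, gave a median of 0.21, with 21 genes higher and 7 lower. That lay above the central 95% of random lists but between the bound of 0.2 set for dropping the explanation and the 0.5 that it needed. The median cannot decide the question where members are also transcribed in other cells of the libraries, which was not tested. The extremes of the second list were Myl2, Myl3 and Tnni3 at 3.79, 3.01 and 2.61 and Tcap at −1.95, the last on 17 and 4 counts. Its 3 most abundant members, Tnnc1, Tnni1 and Gata4, lay at 0.10, 0.18 and 0.19. Over both cardiac lists, 15 of 35 genes were more than 2-fold higher, and 7 were lower. No biological explanation was tested because the design gives no second group.

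Replication-dependent histone genes, a set taken by gene symbol among protein-coding genes, were lower in replicate 2, with 53 of 57 below 0 and a median log2 ratio of −0.78. The sum of their counts differed by −0.39. The 4 whose counts had a posterior SD of 0 had a median of −0.54 and ran from −1.71 for Hist2h4 to 0.38 for Hist2h2be. Fewer cells in S phase are argued against as the whole source by 13 S phase genes, whose median was −0.0039 with an SD of 0.14. Trends with transcript length and GC content are argued against as the whole source. The histone median remained at −0.65 and −0.72 after the median of genes of like length or GC content was subtracted, with 52 and 53 genes below 0. The bin of the shortest genes had a median of −0.13. As the median of a bin was subtracted, a steeper trend within the shortest bin was not tested. A lower yield of RNAs without a poly(A) tail in replicate 2 may account for the pattern, since 19 other such RNAs had a median of −0.80, below the central 95% of random lists, and −0.69 when copies with counts within 1% were taken once. These RNAs are also short, some of them below the 200 nt size minimum, and the length trend was not subtracted from their ratios. For them, a missing tail and a short length cannot be told apart. With copies taken once, only 3 of these RNAs had at least 100 counts in both libraries, with ratios from −1.03 to −0.62, and a biological difference between the embryo pools was not tested.

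The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were lower in replicate 2 (log2 ratios −0.67, −0.36, −0.30 and −0.72) and Xist was higher (0.48, or below 0 under scaling by the spike-ins) in libraries that the labels give as pools of both sexes. A test on other Y-linked genes gave no value, since Zfy1, Zfy2, Usp9y and Uba1y had 0 counts in both libraries.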

How the results depend on the processing

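Of the alternatives, 4 were chosen after seeing the data: the mitochondrial share with nuclear copies that share reads, which was 2.06%, and the list shifts with trends subtracted. Taken over expected counts instead of TPM, the globin share was 15.2%, the hepatic share 3.36% and the embryonic share of globins 1.37%, as counts grow with transcript length. Taken over TPM, the mitochondrial share was 2.45% and the spike-in share 2.49%. The difference between the mature and fetal hepatocyte lists was −7.25 with a pseudocount of 1, −9.00 with 0.01 and −6.78 over members with at least 10 counts. The lead of the highest resident list over the neighbouring lists was 6.17 with a pseudocount of 1 and 6.06 over such members. No sign changed. Pearson's r fell to 0.984 with no filter. The median absolute log2 ratio was 0.16 by library totals, 0.64 by spike-ins and 0.12 for genes with at least 100 counts. The spread of endogenous genes against spike-ins reversed to 0.0066 with each class centred on its own median and to 0.47 with spike-in scaling, as the offset of the spike-ins enters 1 class or the other. Of the lists outside the random range, spike-in scaling reversed the medians of erythroid membrane (−0.54), hepatoblast (−0.59) and cholangiocyte (−0.14), since it moves all genes by about −0.64. Lists inside the range with medians above 0 turned negative as well. The number of lists outside the random range was 12 with TPM ratios, and 11, 13 and 13 with the trends of length, GC content or both subtracted, and the number of shared leading transcripts 15 by counts. Leaving out either replicate returns the value of the other, so it is no check of stability; genes detected ranged from 12426 to 12639 and the globin share from 31.2% to 34.6%. With n = 2, no test between replicates was possible, and ratios of genes under 100 counts are limited by depth.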

Other observations

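Antioxidant enzymes, a list chosen after the data had been seen, were abundant in this globin-rich tissue, and all 10 exceeded 1 TPM in both libraries with a median of 333 ± 6.27 TPM. Gpx1 stood at 6186 ± 15.6, the peroxiredoxin Prdx2 at 1826 ± 87.6, superoxide dismutase (Sod1) at 1207 ± 48.7 and Prdx1 at 943 ± 82.3 TPM. Of the 10, 8 were lower in replicate 2, among them Prdx2 and Sod1 with a log2 ratio of −0.23 each, and the list median was −0.08, inside the central 95% of random lists of like expression. Catalase (Cat) stood at 111 ± 26.5 TPM and was higher in replicate 2 (0.34, counting interval 0.30 to 0.38), although scaling by the spike-ins takes it below 0.

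Transcripts of 12 blood cytokines and growth factors, a list also chosen after the data had been seen, had a median of 4.78 ± 0.148 TPM. Igf2 was the highest at 334 ± 7.67 TPM, followed by the chemokine Cxcl12 at 48.3 ± 7 TPM. Stem cell factor (Kitl) stood at 9.67 ± 3.37, thrombopoietin (Thpo) at 3.13 ± 0.53 and erythropoietin (Epo) at 0.98 ± 0.17 TPM, the last on 20.0 and 23 counts. The receptors Epor and Kit belong to the fixed lists, and Epor stood at 118 ± 0.658 TPM. Kitl was higher in replicate 2 (log2 ratio 0.47, counting interval 0.37 to 0.58), and 9 of the 12 genes lay above 0 with a list median of 0.15. Both this median and the ratio of Kitl fall below 0 under scaling by the spike-ins.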
